A study of Oryctolagus cuniculus with 3 samples.

How the data were processed

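Cumulus-oocyte complexes, the oocyte with the somatic cells that surround it, were taken from the ovaries of rabbits (Oryctolagus cuniculus) kept under 3 ammonia concentrations, per the labels. The labels describe 150 female rabbits, 35 days old at the start and kept for 4 weeks. There was 1 library in each group, labelled CG (under 3 ppm), LAC (10 ppm) and HAC (30 ppm), and how many animals gave RNA to a library is not given in the sources used here. Per the labels' protocols, ribosomal RNA was depleted with a kit and the second strand was marked with dUTP, a step meant to keep strand. Some deposited long non-coding loci, such as MSTRG.15412 and MSTRG.13207, have no strand. Whether the deposited values are resolved by strand is therefore uncertain. The submitters' processing notes name fastp, HISAT2 and the genome build OryCun2.0, without versions or settings. The step that assembled transcripts and estimated their abundance is not given in the sources used here.

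Each deposited file stacks a block of gene statistics, a block of long non-coding classes, a block of mapping statistics, a gene table and a table of long non-coding transcripts. The gene table has 39681 loci with an estimated count and an FPKM value (fragments scaled by transcript length and library size), per the file headers. The long non-coding table has 15335 transcripts at 13113 loci, each with the authors' coverage, a signal of mean read depth, and their FPKM. The deposited counts are not whole read counts. At the loci with 1 long non-coding transcript and a coverage above 2 (8651 in CG, 8638 in LAC), 100% of counts equalled coverage times length divided by 75, to within rounding, while the reads have 150 bases. A deposited count thus stands for about 0.5 reads, and counting intervals were computed on halved counts.

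The gene tables in the files of LAC and HAC were the same in every cell of all 39681 rows, and both are headed LAC. They were used once, as the library labelled LAC, and 2 of 12 columns of per-sample values were left unused for this reason. No gene-level values of the library labelled HAC were analysed here, so the planned gene comparisons with HAC were made on long non-coding loci alone. The label of the shared table is uncertain. Its FPKM maximum of 39492 is the one the statistics block of the HAC file gives, where the block of the LAC file gives 86394. The valid reads of the mapping blocks are also exchanged between both files. The LAC column of the long non-coding table belongs to the same library as the shared table: its coverage gave the table's count within 5% at 97.3% of 8638 loci with 1 transcript, against 4.15% of 8795 for the HAC column. All groups are therefore named by the library's label, and a direction drawn from LAC or HAC assumes that label.

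Estimated counts were scaled to CPM, a count relative to library size, with trimmed mean of M values factors (TMM), computed from their formula with 30% of ratios and 5% of levels trimmed. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1 were used. Differences are on the log2(value + 1) scale, which understates the change of low genes. A gene passed the size rule when the difference was at least 1 and the higher library had at least 10 counts. Long non-coding FPKM values were summed per locus and used as deposited, with at least 1 FPKM in the higher library. The gene FPKM values served as an alternative only. Between genes they are on an uncertain scale, since only 6.17% of 1-transcript loci in CG had a gene FPKM within 10% of the transcript's FPKM. With 1 library per group no test, standard error or p-value was computed.

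Coding genes are rows with a RefSeq messenger RNA, and unannotated loci are assembled rows without a RefSeq transcript, which can still lie over coding genes, as the mitochondrial rows do. Names come from the files. A LOC name was looked up by its gene number in the RefSeq table of assembly mOryCun1.1, which gave a symbol to 832 of 13817, and no coordinate of that assembly was used. For 39 gene lists fixed before the data were examined, the median over members with a mean of at least 0.5 CPM over both libraries was set against 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these libraries. The library that stands apart is, for a locus with a range of at least 1 over the 3 libraries, the one farthest from the mean of the others. Long non-coding loci outside genes were paired with the nearest coding gene within 100 kb and compared with 10000 shuffles of partners.

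Named genes are the 10 with the largest difference in each direction among genes with a symbol of their own in the files and at least 10 CPM in the higher library, up to 2 members of each list with the highest mean and 2 with the largest difference, and 5 long non-coding loci in each direction with at least 5 FPKM. Fold values of named genes are ratios of CPM without a pseudocount, with exact binomial 95% intervals that cover counting error only. Not every list member that this rule names is printed. Names outside this rule, such as CYP19A1, BMP6, SYCP3, PIWIL2, the zona pellucida genes, the mitochondrial loci and the further members past the size rule, were chosen after their values were seen. The floor for a gene at 0 was 3 reads, or 6 estimated counts.

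The steps were tested on simulated data drawn from the real genes' means for LAC against CG, run on 28514 genes. Of 50 genes changed 3-fold, 96% passed the size rule, of 50 changed 4-fold 98%, of 50 changed 8-fold 100%, and of 50 changed 2-fold, which lies on the threshold, 20%. None of the 28314 unchanged genes passed. The changed genes were drawn from those with a mean of at least 100 reads. The simulated libraries differed by counting error only, without spread between animals or libraries. That no unchanged gene passed was therefore nearly fixed in advance, and the rate of false calls between real libraries is not known. Of 500 unchanged lists, 5.60% lay outside the central 95% of random lists. The alternatives changed the pseudocount, the filter on level, the scaling, the size rule, the unit of transcripts, the list average and the distance to neighbours. Gene FPKM, TMM factors from coding genes and loci with 1 transcript were added after seeing the data.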

Results

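RNA of cumulus-oocyte complexes was sequenced to examine how long non-coding and messenger RNA differed with the ammonia concentration rabbits were kept under. There was 1 library per group, so the differences below have no replicate check. The estimated counts summed to 78461882 in the library labelled CG and 68523767 in the library labelled LAC, where a count stands for about 0.5 of a read assigned to a locus. Mapped reads made up 92.7% of the valid reads in the file of CG, 93.2% in that of LAC and 90.3% in that of HAC. Spliced reads made up 22.01%, 16.2% and 19.9%. The valid reads are exchanged between the files of LAC and HAC. The mapping block in the file of LAC has 72520954 valid reads, as has the statistics block that gives the shared gene table's FPKM maximum. By this link 93.2% mapped and 16.2% spliced belong to the library whose gene table was used. Which ammonia group that library came from is uncertain. Gene-level values labelled HAC were not analysed here, and whether the gene table labelled LAC comes from the LAC or the HAC animals is uncertain.

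The first comparison asked how gene expression in the library labelled LAC differed from that in the library labelled CG. Genes of the oocyte were lower in LAC. Of the 30 genes of the oocyte list, 26 were detected and 24 were lower by 1 or more on the log2 scale, with none higher. The list's median was -2.04, at percentile 0 of 10000 random lists of the same size and level. BMP15, a growth factor secreted by the oocyte, had 1771 CPM in CG and 345 CPM in LAC, 5.14-fold lower (95% interval 5.04 to 5.24). WEE2, an oocyte kinase that keeps meiosis arrested, was 5.69-fold lower, KPNA7 6.92-fold and MAEL, a germ-line protein of the piRNA pathway, 7.74-fold. The zona pellucida genes ZP1, ZP2, ZP3 and ZP4 differed by -1.90, -2.37, -2.16 and -1.95. BMP6, at 0.06, and SYCP3, at -0.28, did not pass the size rule. Under each scaling tried the list's median stayed between -2.07 and -1.88.

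**Figure D1:**
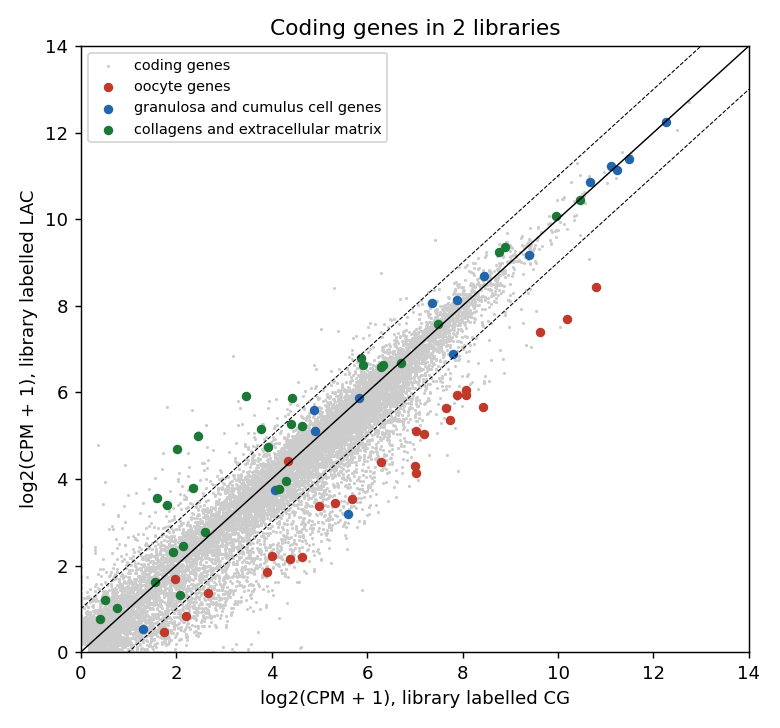
Each point is a coding gene, with log2(CPM + 1) in the library labelled CG on the horizontal axis and in the library labelled LAC on the vertical axis, the solid line marking equal values and the dashed lines a difference of 1. Of the 26 oocyte genes 24 lie below the lower dashed line, and 1 of the 16 granulosa and cumulus genes does.

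Genes of the granulosa and cumulus cells, the somatic part of the complex, had a median difference near 0, with members on both sides. The median over 16 detected genes was 0.01, at percentile 76.5 of the random lists, with 8 above 0 and 8 below. It was -0.03 with median-of-ratios scaling and -0.15 as a mean. GJA1, which encodes the gap junction protein connexin 43, had 4933 CPM in CG and 4814 CPM in LAC. INHBB, an inhibin and activin subunit, had 2881 and 2668 CPM. CYP19A1, the aromatase gene, had 163 and 265 CPM, and IHH, a hedgehog ligand, had 221 and 118 CPM, 1.88-fold lower (1.81 to 1.95). The 1 gene past the size rule was SLC18A2, a monoamine transporter, 5.80-fold lower. The cumulus expansion genes had a median of 0.27 (percentile 99.8), with 2 of 13 higher: PTX3, 2.82-fold, and ADAMTS1, 2.20-fold. VCAN, the proteoglycan versican, had 2933 and 2921 CPM, and CD44, the hyaluronan receptor, was 1.77-fold lower. With members of at least 5 CPM alone the expansion list had a median of 0.10 (percentile 95.4). The gonadotropin and steroid receptors had a median of 0.33 (percentile 99.9) with 0 of 10 past the rule, and FSHR, the receptor for follicle-stimulating hormone, had 346 and 414 CPM.

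Cell cycle genes were lower in LAC. Of 28 detected, 11 were lower by 1 or more and 0 higher, with a median of -0.90 and a percentile of 0. AURKA, a mitotic kinase, was 3.48-fold lower and PCNA, the sliding clamp of DNA replication, 2.97-fold lower, while CCND2, the cyclin D2 gene, had 1365 and 1391 CPM. These genes were lower in the same library as the oocyte genes.

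Genes of the extracellular matrix were higher in LAC. Of 31 detected, 8 were higher by 1 or more and 0 lower, and the median was 0.47, at percentile 100. The 8 were COL1A1, COL1A2, COL3A1, COL5A2, DCN, POSTN, TNC and TIMP1. COL5A2, a fibrillar collagen, was 8.16-fold higher (6.73 to 9.97) and DCN, the proteoglycan decorin, 6.97-fold (5.95 to 8.25), from 3.03 and 4.46 CPM in CG. The abundant SPARC, at 1405 and 1387 CPM, and THBS1, at 991 and 1085 CPM, did not pass the rule. The stromal fibroblast genes, which share matrix members with that list, had a median of 0.76 (percentile 100) with 5 of 10 higher and MFAP4 lower.

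Markers of blood-derived cells had at most 47.3 CPM and went both ways. The macrophage and monocyte genes had a median of 0.63 (percentile 100), with 4 of 12 higher and 1 lower, and together made up 0.00623% of scaled counts in CG and 0.00424% in LAC. MRC1, the mannose receptor, had 0.73 CPM in CG and 8.04 CPM in LAC, and MSR1, a scavenger receptor, had 47.3 and 8.20 CPM. The lymphocyte genes had a median of -0.89 (percentile 6.42) over 4 genes, with MS4A1, a B cell marker, at 14.01 and 2.83 CPM, and the neutrophil and mast cell genes -2.55 (percentile 0.01) over 3. Among these were HDC, at 15.0 and 1.71 CPM, and KIT, which oocytes also express, at 34.9 and 5.12 CPM. The red blood cell genes had 2 detected members and no percentile. The endothelial genes had a median of 0.25 (percentile 93.1), with 1 of 7 higher and 2 lower, but a mean of -0.33 (percentile 35.0), and their share of scaled counts went from 0.0061% to 0.0020%. The skeletal muscle genes had a median of 1.33 (percentile 99.9) over 3 genes, all at most 13.4 CPM, and a mean of 0.59 (percentile 97.4), with CKM 3.50-fold lower. The smooth muscle and pericyte genes were at percentile 92.5 and, as a mean of 0.34, at 99.8, with 3 of 13 higher, DES, LMOD1 and PDGFRB, and 0 lower. The adipocyte genes were at 11.3, with 0 of 4 higher and 1 lower, DGAT2. The surface and oviduct epithelial genes had a median of 0.35 (percentile 95.9) but a mean of -0.33 (percentile 40.4), with 1 of 5 higher and 2 lower, CDH1, 5.02-fold, and EPCAM, 3.58-fold. Their share of scaled counts went from 0.0086% to 0.0026%.

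In the lists of ammonia metabolism and cell stress, from 0 to 4 members passed the rule, where 1.89% of all coding genes were higher and 11.01% lower. The ammonia, glutamine and urea genes had a median of -0.27 (percentile 15.2) with 2 of 22 lower. GLS2, the liver-type glutaminase, was 4.73-fold lower and SLC38A1, a glutamine transporter, 2.04-fold lower. The antioxidant genes had 0 of 24 past the rule and a median of -0.08 (percentile 71.9). HMOX1, heme oxygenase, had 6.18 and 3.34 CPM. The apoptosis list had 1 of 18 higher and 3 lower (percentile 42.7), with CASP6, a caspase, 3.41-fold lower, and CYCS, the cytochrome c gene, 11.7-fold higher (9.96 to 13.9), from 4.02 to 47.1 CPM. The symbol CYCS came from the RefSeq table and not from the files. The heat shock list had a median of -0.44 (percentile 1.45) with 0 of 12 past the rule, and its mean was at percentile 11.01. In the unfolded protein list, at percentile 11.9, ATF4, a transcription factor of the integrated stress response, was 6.76-fold lower and HSPA5, the chaperone BiP, had 1124 and 945 CPM. The p53 list was at percentile 4.78 with 4 of 19 lower.

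The interferon genes had a median of 0.37 (percentile 99.98) with 5 of 21 higher, IFIT2, OAS3, IFI44, IFI44L and USP18, and 2 lower, IRF1 and XAF1. MX1, an antiviral protein, had 46.1 and 74.6 CPM. The interferon list was smaller as a mean, at 0.22 (percentile 99.8), and with the 12 members of at least 5 CPM, at 0.19 (percentile 99.0). The inflammation list was at percentile 96.8 with 0 of 16 past the rule. The luteal list had a median of 0.37 (percentile 99.8) with 1 of 7 higher, TIMP1, and 1 lower, PLIN2, a lipid droplet protein, and a mean of 0.23. The cytosolic ribosomal proteins had a median of 0.08 (percentile 98.0) with 1 of 43 higher and 1 lower, and the autophagy list a median of 0.06 (percentile 98.1) with 0 of 20 past the rule, its mean being -0.06. In the main setting the other lists lay inside the central 95%: theca cells at 87.8, steroid synthesis at 76.0, cholesterol synthesis at 45.2, nuclear-encoded respiratory chain genes at 60.3, mitochondrial dynamics at 97.3, glycolysis at 3.90, TGF-beta signalling at 61.8, PI3K signalling at 34.0, gap and tight junctions at 7.67, the circadian clock at 83.9 and immediate early genes at 58.1. The gap and tight junction list had 4 of 10 lower and 0 higher, and was at percentile 0.02 as a mean and 1.41 with members of at least 5 CPM alone. The immediate early genes were at 97.7 with members of at least 5 CPM alone. BMP15 and GDF9 belong to the TGF-beta list as well as the oocyte list. Of 37 lists with at least 3 detected members, 4 were under percentile 2.5 and 10 above 97.5. For independent lists of unrelated genes 1.85 would lie outside. Members of a list can vary together, and lists share members, as the luteal and receptor lists share LHCGR, PRLR and PTGFR. That number is therefore not the one to expect here. The random lists came from coding genes, which had a median of -0.14. A list with a median near 0, such as the ribosomal and autophagy lists, can therefore rank high. No member of the list of mitochondrially encoded genes was matched, because the files give the mitochondrial sequence, NC_001913.1, as 2 unannotated loci, MSTRG.1 and MSTRG.2, which span 2650 to 17245 on opposite strands. They had 12845 and 11137 CPM in CG and 10070 and 8440 CPM in LAC, differences of -0.35 and -0.40, and do not give values of single genes.

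**Figure D2:**
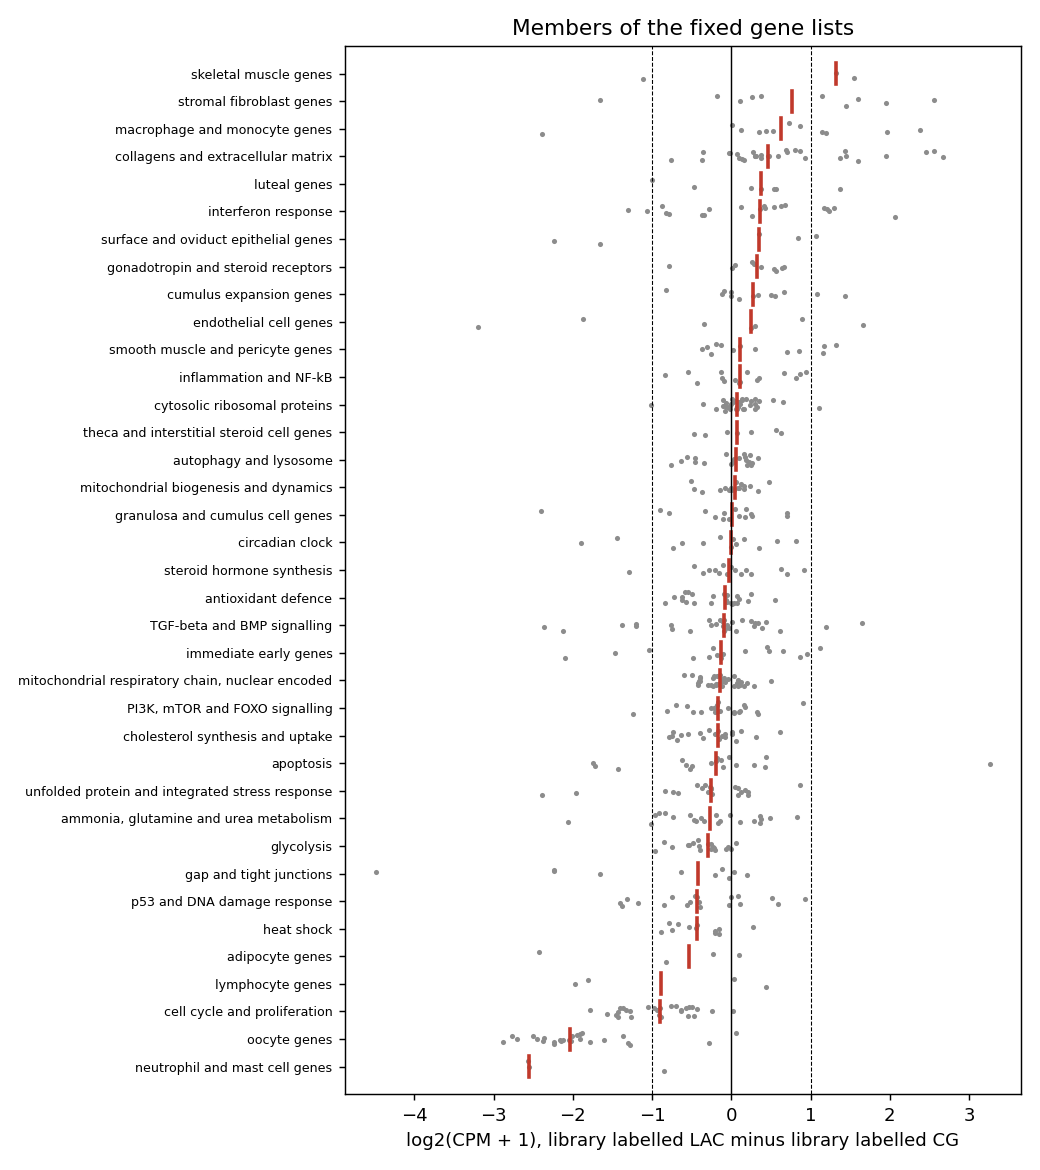
Each point is a detected member of a fixed list, with the log2(CPM + 1) difference between the library labelled LAC and the library labelled CG on the horizontal axis, and the red bar is the list's median. The oocyte list has its median at -2.04 and the list of collagens and extracellular matrix at 0.47.

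Of 15009 coding genes with enough counts, 283 were higher in LAC and 1653 were lower, with a median difference of -0.14. Of 12144 unannotated loci, 910 were higher and 746 lower, with a median of 0.27. Over all 29030 loci 1227 were higher and 2470 lower, so that 33.2% of the calls were higher. TMM factors from coding genes alone shifted the log2 ratio of every locus by 0.18. Then 1842 were higher and 2046 lower, 47.4% of the calls being higher, with 396 coding genes higher and 1340 lower. A pseudocount of 0.1 gave 4582 higher and 5027 lower.

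TNFRSF11B, which encodes the decoy receptor osteoprotegerin (OryCun2.0, sequence NC_013671.1, 134828524 to 134858054), had 8.07 CPM in CG and 114 CPM in LAC, 14.2-fold higher (12.6 to 15.9). VGLL3 was 21.4-fold higher (15.0 to 30.3), GTF3C6 9.99-fold and the small nucleolar RNA SNORA63 7.99-fold. MMP14, a membrane-bound matrix metalloproteinase, was 7.85-fold higher, IGSF10 7.90-fold, TMPRSS11A 7.29-fold and SLC25A51, the mitochondrial NAD carrier, 7.13-fold. In the other direction, FEM1B had 239 and 17.1 CPM, 13.96-fold lower (12.8 to 15.2), and RSPO2, a Wnt signalling agonist that oocytes secrete, 204 and 22.6 CPM, 9.04-fold lower (8.39 to 9.74). GALNT13 had 23.7 CPM in CG and 6 estimated counts in LAC, 268-fold lower (91.4 to 1301). GJA4, the gene of connexin 37, which joins the oocyte to its granulosa cells, had 23.0 CPM and 5 estimated counts, 313-fold lower (108 to 3234). GSDMA had 10.4 CPM in CG and no count in LAC, at least 118-fold lower. TEK, the angiopoietin receptor, was 11.05-fold lower, SLC3A1 11.5-fold, SLC6A4, the serotonin transporter, 15.7-fold, SHISA9 23.3-fold and MOGAT2 31.7-fold.

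The long non-coding table covered all 3 libraries. Of 9588 loci with at least 1 FPKM in LAC or CG, 1265 were higher in LAC and 1031 lower. Of 8647 loci, 710 were higher in HAC than in CG and 488 lower. Of 9939 loci, 1455 were higher in HAC than in LAC and 1218 lower. The split followed the settings. With median-of-ratios factors 652 were higher and 1402 lower in LAC against CG, 712 and 572 in HAC against CG, and 1742 and 644 in HAC against LAC. Without any change of scaling, LAC against CG turned to 60 higher and 193 lower with a pseudocount of 5, 82 and 153 at 10 FPKM or more, and 53 and 170 with a size rule of 2. HAC against CG turned to 70 and 102 with a pseudocount of 5 and 81 and 107 at 10 FPKM or more, and HAC against LAC to 2090 and 2733 with a pseudocount of 0.1. Intronic loci had 517 higher and 179 lower in LAC against CG with a median of 0.46. In HAC against CG they had 181 higher and 131 lower with a median of 0.09. Over all loci the medians as deposited were 0.34 and 0.09, and with median-of-ratios factors 0.03 and 0.05. Values by class are given as deposited only. Junction-sharing loci, which share splice sites with an annotated gene, had 42 higher and 126 lower in LAC against CG.

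LAC was the library that stood apart most often. Of 3986 loci with a range of at least 1, LAC stood apart at 2240, or 56.2% (Wilson 95% interval 54.7 to 57.7), HAC at 1063, or 26.7% (25.3 to 28.1), and CG at 683, or 17.1% (16.0 to 18.3), where exchangeable libraries would each give 33.3%. With FPKM as deposited, LAC was above both others at 1321 of its loci and below them at 919. This split is not given here under other scalings. The split of LAC against CG turned to 652 higher and 1402 lower with median-of-ratios factors, so the direction may follow the scaling. The loci are not independent replicates, and the intervals treat them as if they were.

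**Figure D3:**
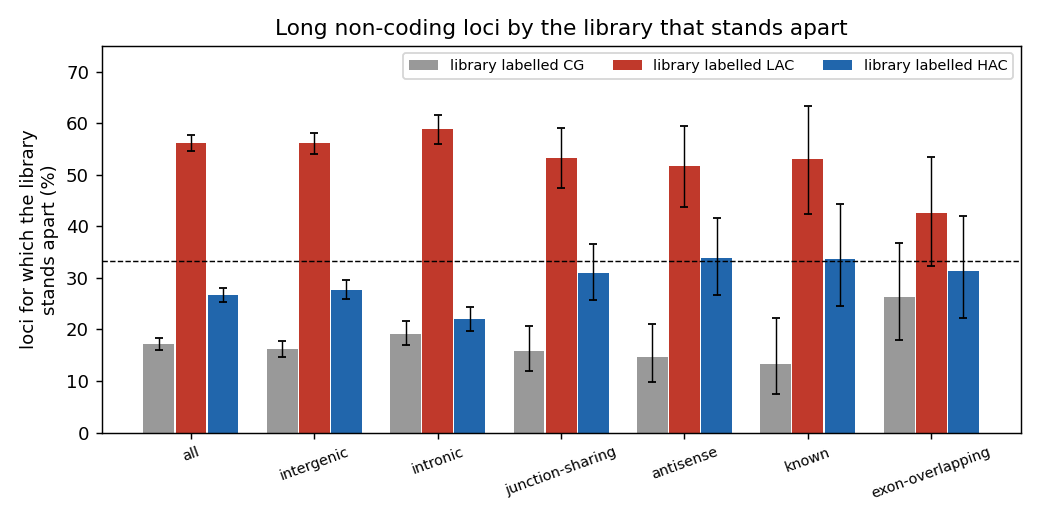
Bars give the percentage of long non-coding loci in each class for which a library lies farthest from the others, with Wilson 95% intervals over loci and a dashed line at an even share of 33.3%. Over all loci the library labelled LAC has 56.2% and the library labelled CG 17.1%.

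The intergenic locus MSTRG.18562 had 165 FPKM in CG, 849 FPKM in LAC and was listed at 0 in HAC. The antisense locus MSTRG.11177, at the gene LOC108177453, had 160 FPKM in CG and was listed at 0 in LAC and HAC. The intergenic locus MSTRG.15047 had 58.9 FPKM in CG, 0.84 in LAC and 57.4 in HAC. The intronic locus MSTRG.13207 in COL6A6 had 0.06 FPKM in CG, 15.3 in LAC and 10.0 in HAC. The known long non-coding gene LOC108175901 had 0.65, 23.3 and 0.53 FPKM. The junction-sharing locus MSTRG.24584 at FAU, a ribosomal protein gene, had 2 FPKM in CG and 67.4 in HAC and was listed at 0 in LAC. Several such loci overlap another locus on the opposite strand, as MSTRG.5517 and MSTRG.5518 do at LOC108176754, so the assembly's split of reads between overlapping transcripts leaves their values uncertain.

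The differences of long non-coding loci and of their nearest coding genes were weakly correlated in LAC against CG. Across 3225 pairs within 100 kb, Spearman's rho between the log2 differences was 0.17, where 95% of shuffles lay between -0.03 and 0.04. Across 1380 pairs within 10 kb it was 0.21. Of 93 pairs in which both passed the size rule, 62 differed in the same direction, where shuffled partners gave 43.3 on average and 34 to 52 in 95% of shuffles. Within 10 kb it was 19 of 30, where 95% of shuffles gave 9 to 19. These shuffles were added after the counts were seen. For 2983 intronic loci and their host genes rho was 0.25. These are relations across genes, which are not independent replicates.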

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

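The tests of the 20 loci, the mitochondrial rows and the rescaled correlation were chosen after their result was seen, and the correlation with its bounds before. Counts in rows without a RefSeq messenger RNA made up 34.2% in the library labelled LAC and 24.6% in the library labelled CG, a gap of 9.55 percentage points that lies outside the gene lists. These rows include 2 mitochondrial ones, which span coding genes and took 2.42% of the counts in CG and 1.83% in LAC. With them set among the coding genes the shares were 32.3% in LAC and 22.2% in CG, a gap of 10.1 percentage points. The unannotated locus with the most counts in LAC, which the files name WDR74, took 2.91% of the counts there and 0.75% in CG.

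A few loci account for part of this gap. The 20 unannotated loci with the most counts over both libraries were taken out of the rows without a RefSeq messenger RNA and of the total. The shares were then 17.4% in LAC and 12.8% in CG. That gap was 4.65 percentage points, 48.7% of the full gap. Since the total shrank too, 48.7% is not the part of the full gap that all other loci carried. The mitochondrial rows were also set among the coding genes and the other 18 taken out in the same way. The shares were then 17.0% in LAC and 12.4% in CG, a gap of 4.61 percentage points. It was 45.5% of the gap of 10.1 percentage points, again on a smaller total. For genomic DNA and for unspliced transcripts of the host genes the deciding value was the correlation across 3266 intronic loci between the gain in FPKM and the host gene's level. The correlation was 0.23 (95% interval over loci 0.20 to 0.27), which is past the bound set against DNA and for unspliced transcripts. That bound was wrong, because a plain scale factor between libraries also makes the gain follow the level: with median-of-ratios factors the correlation was 0.10 (0.07 to 0.14), and with factors from intronic loci 0.03. Genomic DNA and unspliced transcripts may each contribute and cannot be told apart here. An effect of ammonia on these transcripts was not tested, since each group has 1 library.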

How the results depend on the processing

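No paired analysis was possible because each group has 1 library. The alternatives with gene FPKM, TMM from coding genes and loci with 1 transcript were chosen after seeing the data. Counts of loci past the size rule followed the pseudocount, the level and the size rule, by their construction. For all loci in LAC against CG, higher and lower, they were 4582 and 5027 with a pseudocount of 0.1, 348 and 1167 with 5, 503 and 1342 at 10 CPM or more, and 117 and 500 with a size rule of 2. For coding genes they were 943 and 2740, 112 and 909, 151 and 1090, and 41 and 323. For long non-coding loci, in LAC against CG, HAC against CG and HAC against LAC, they were 4398, 2683 and 4823 with a pseudocount of 0.1, 253, 172 and 298 with 5, 235, 188 and 260 at 10 FPKM or more, and 223, 145 and 327 with a size rule of 2. TMM from coding genes gave 1842 loci higher, which follows from its shift of every locus's log2 ratio by 0.18. Gene FPKM gave 179 coding genes higher. At 99.9% of 18616 genes its log2 ratio between the libraries lay within 0.05 of 1 offset from that of the counts. Its scale was shifted by -0.06 from the main one, and the pseudocount acts on another unit. How much each contributes was not tested. With loci scaled to the same total, 27.6% of the long non-coding calls in LAC against CG were higher, against 55.1% as deposited, and 43.1% against 59.3% in HAC against CG. The share of loci where LAC stood apart was 51.1% with median-of-ratios factors, 49.0% at 10 FPKM or more and 54.4% with a pseudocount of 0.1. TMM from coding genes adds about 0.18 to each gene's log2 ratio, and less to the difference of low genes. It moved the medians of cholesterol synthesis to -0.0089, the nuclear-encoded respiratory chain to 0.035, mitochondrial dynamics to 0.21 and glycolysis to -0.12. TGF-beta signalling moved to 0.082, PI3K signalling to 0.0078 and ribosomal proteins to 0.25. The autophagy list was -0.056 as a mean, against a median of 0.063. In 15 list values, over 13 lists, the sign changed. As a mean these were granulosa and cumulus (-0.15), endothelial (-0.33), epithelial (-0.33) and autophagy. With members of at least 5 CPM alone they were theca (-0.054), smooth muscle (-0.010) and immediate early genes (0.16), with median-of-ratios scaling granulosa and cumulus (-0.026), and with TMM from coding genes steroid synthesis (0.14), antioxidant (0.093), circadian clock (0.15), immediate early genes (0.0081), respiratory chain, TGF-beta and PI3K signalling. In 12 list values, over 9 lists, the percentile changed sides of the central 95%. As a mean, gap and tight junctions went from 7.67 to 0.02, smooth muscle from 92.5 to 99.8, inflammation from 96.8 to 98.9, mitochondrial dynamics from 97.3 to the bound of 97.5, heat shock from 1.45 to 11.01, autophagy from 98.1 to 93.8 and skeletal muscle from 99.9 to 97.4. With members of at least 5 CPM alone, gap and tight junctions went to 1.41, immediate early genes from 58.1 to 97.7, cumulus expansion from 99.8 to 95.4 and autophagy to 95.6. With TMM from coding genes inflammation went to 97.6. Of 179 list values under alternatives, 171 moved by less than the spread over members. Of 40 values of named genes, 12 moved beyond counting error and 0 changed direction. The direction was fixed in advance, since a pseudocount keeps the sign and median-of-ratios factors shifted every gene's log2 ratio by only -0.03. The neighbour correlation was past its shuffles at both distances. Estimated counts near 0 limit folds of low genes, and FPKM at 0 gives none.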

Other observations

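The tests of scaling, of reads outside coding genes and of stromal markers were chosen after the result was seen. The second list of germ-line genes was written after the first list's result and before its own was seen.

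The lower oocyte genes in the library labelled LAC may come from a smaller share of oocyte RNA in that library. A second list of 55 germ-line genes had 43 detected members, of which 31, or 72.1%, were lower by 1 or more and 0 higher, with a median of -1.51. The exceptions include PIWIL2, with 195 and 156 CPM. The 72.1% was just past the bound set in advance. Lower levels of these genes within each oocyte would lower both lists as well, so the second list cannot tell these apart. For scaling as the whole cause, the list's median was -1.88 at its highest under other factors. Those factors moved the log2 scale by only -0.03 to 0.18, so the outcome was fixed in advance and decides nothing. Reads lost to sequence outside coding genes are argued against by the gap of -2.04 between the medians of the oocyte list and the granulosa and cumulus list. Whether a smaller share came from how complexes were collected or from exposure stays open, as does which animals the library came from.

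The stromal and matrix genes higher in LAC might reflect more stromal cells in the sample, and the tables do not decide. Of 2 detected stromal markers that do not encode matrix proteins, NR2F2 was higher by 1 or more and PDGFRA was not, 50% (exact 95% interval 1.26 to 98.7), which is too few to tell. FBLN1, MFAP4 and OGN, which encode matrix proteins but are not in the matrix list, were left out after their values were seen. With them 1 of 5 was higher, or 20%, and 1 was lower. That is under the bound of 50% set against more stromal cells, so the outcome turned on leaving them out.

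A further hypothesis was that the library labelled HAC had lost the same RNA as the library labelled LAC. The 91 long non-coding loci in genes lower by 1.5 or more in LAC had a median difference of -0.98 in LAC against CG and 0.18 in HAC against CG. Since the loci were chosen by their host genes in LAC, the value of -0.98 follows in part from that choice. In HAC against CG the median of the 91 loci was 0.081 above that of 3192 other hosted loci (95% interval -0.12 to 0.27). The hypothesis needed a value under -0.5. None of these loci lies in a gene of the oocyte list, so the oocyte genes themselves were not read in HAC.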
